A study of Canis lupus familiaris with 9 samples.

How the data were processed

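Bulk RNA sequencing was analysed in 9 bladder tumour samples from dogs, 1 library per sample. Per the labels' protocols, tissue was taken through a cystoscope, placed in a phenol-based lysis reagent and frozen, and total RNA was purified on silica columns before standard short-read library preparation. The labels give the same diagnosis, invasive urothelial carcinoma, to every sample and name no normal tissue, batch, sex, treatment or subtype. The 9 samples therefore form 1 group, and no comparison between groups was made. The samples are called tumours 1 to 9 in accession order, and the number is only a name. The labels do not state that the 9 samples came from 9 dogs. The p-values of tests across samples therefore concern only the spread between these samples, which may in part be technical. Those given at the end for neighbouring identifiers come from shuffling the order of genes and do not measure that spread.

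The authors deposited estimated counts of reads per gene, not scaled to a common depth, as the values show. Of all values, 30.8% are not whole numbers, as a method that divides reads between features gives. Reads were processed with the CanFam3.1 dog genome build, per the submitters' processing notes. The aligner, the quantification tool, the annotation release and any filter are not given in the sources used here. The table has 32183 rows, all Ensembl dog gene identifiers, and 11934 of them hold 0 in every tumour. All 9 columns were matched to 1 sample each by the name in its title, and no column was left over. For tumour 1 the match is not exact: the column name lacks the first letter of the name in the title, and no other title holds it. The estimated counts were rounded to whole numbers before use, so a value listed here as 0 was at most 0.5. Strand use in counting is not given, so reads of overlapping and antisense genes, and of near-identical gene copies, may be split or merged in ways that cannot be checked.

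The table does not pair identifiers with gene symbols, and the reference table at hand holds no Ensembl identifiers: 0 of the identifiers matched a symbol. The 28 gene lists fixed before the data were examined (urothelial, stromal, immune, proliferation and other markers), their coherence and variability tests and the planned correlations between list scores could therefore not be run, and no gene, cell type or pathway is named. Genomic positions are not given for the same reason.

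Total counts per tumour ran from 19750014 to 132750295. A count of 3, used as the floor, corresponds to 0.152 CPM (counts scaled to a common library total) in the shallowest library and 0.0226 CPM in the deepest. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Counts were normalised with TMM factors in edgeR 4.0.16 (R 4.3.3), and genes with a mean of at least 1 CPM over the tumours were tested, with normalisation factors computed again after the filter. Log2 CPM used a prior count of 2. For each gene, the negative binomial deviance under an intercept-only model at the trended dispersion was set against a chi-square distribution on n - 1 degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene past it is called variable: it differed between tumours by more than genes of like abundance did. The excess is the log2 ratio of the deviance to its degrees of freedom. The fit was repeated 9 times with 1 tumour left out.

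The test was checked on simulated data with 50 genes raised in each of 4 ways: 8-fold or 64-fold, in 1 or in 3 libraries. At the dispersion trend of the 9 libraries (13558 genes), the chi-square reference made 152 calls, of which 61 were false. A second reference was then built: 20 whole data sets were simulated at the fitted means and trended dispersions, the trend was estimated again in each, and the deviances were pooled in 40 bins of mean CPM, with a gamma distribution for the far tail. On the same simulated data it made 88 calls, of which 5 were false. It recovered 82% of the genes raised 64-fold in 3 libraries, 62% of those raised 64-fold in 1 library, 14% of those raised 8-fold in 3 and 8% of those raised 8-fold in 1. The simulated data were drawn from the model on which the second reference is built, with every gene at the trend. Its low share of false calls was thus in part set in advance and may not hold for the measured data. The chi-square reference was the one fixed before the data were examined and gives the main counts. The simulated reference was added afterwards and its count stands beside them.

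Detection was described as genes with at least 1 count, on the deposited counts and after binomial thinning of every library to the lowest total. Genes were placed in abundance classes by their median CPM in the 8 other tumours. Principal components were taken from centred log2 CPM. Each was given the sign that made it rise with the share of genes at negative log2 CPM in a library. The sign of its correlation with total counts or genes detected is thus in part set in advance. Correlations across tumours used Pearson's r and Spearman's rho with two-sided exact permutation over all 362880 pairings, adjusted over 3 relations, of which that between total counts and genes detected was added after seeing the data. Dixon's gap-to-range rule was applied to 13 measures. Alternatives tried were DESeq2 1.42.0 size factors and dispersion outliers, no filter, filters at 5 and 100 CPM, a threshold of 0.01, a prior count of 0.5, each tumour left out, and tumours 2, 4 and 6 left out together. The last of these, the filter at 100 CPM and the thinning were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 served for the remaining steps. The rule for genes to be named asked for symbols. Without them, 4 identifiers are printed: among variable genes past the threshold in every leave-one-out fit, and among those lost in at least 1, the gene with the largest excess whose farthest tumour lay above the others and the one whose farthest tumour lay below.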

Results

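The data are gene expression profiles of 9 urothelial carcinomas of the canine bladder, the epithelial tumour of the urinary tract lining, biopsied after screening of Scottish Terriers by urinalysis and ultrasonography. The Scottish Terrier is a breed at high risk of this cancer. With a single diagnosis and no normal tissue among the labels, the question the data can address is how alike these tumours were and which genes set them apart. Tumour 4 had the lowest total, 19750014 counts, and tumour 5 the highest, 132750295 counts, a ratio of 6.72. The totals of the other 7 were 91674042 in tumour 1, 22806202 in tumour 2, 69660376 in tumour 3, 46405805 in tumour 6, 105972471 in tumour 7, 98170567 in tumour 8 and 66228689 in tumour 9. The 10 most abundant genes held 5.45% ± 0.69 of the counts (SD, n = 9), so no library was dominated by a few genes. No pair of libraries agreed within sampling noise, as a library deposited again would. The smallest chi-square per degree of freedom over genes was 819, between tumours 5 and 9. This does not show that the tumours came from separate dogs.

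The number of genes with at least 1 count differed between tumours. Tumour 7 had counts for 17834 genes and tumour 8 for 16852, while tumour 4 had counts for 11573 and tumour 2 for 10678. The mean was 14080 ± 2346 genes (SD, n = 9). Genes detected rose with the log2 total count across tumours (Pearson r = 0.86, p = 0.00402, adjusted p = 0.00603; Spearman rho = 0.85, p = 0.00607, adjusted p = 0.0182, two-sided exact permutation tests). Without tumours 2 and 4, the 2 tumours farthest from the median log2 total, r was 0.72. After every library was thinned to the total of tumour 4, tumour 7 still showed 16452 genes, tumour 8 showed 15793 and tumour 5 showed 15048, against 10632 in tumour 2 and 11573 in tumour 4. The mean after thinning was 13570 ± 1902 genes (SD, n = 9), so read depth alone did not account for the spread. The relation to the total count was not computed on thinned counts.

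The genes listed at 0 in tumours 2, 4 and 6, the 3 shallowest libraries, included moderately abundant ones. Of the genes with a median of 10 to 100 CPM in the 8 other tumours, tumour 4 listed 16.7% at 0 (1049 of 6287), tumour 2 listed 13.96% (885 of 6341) and tumour 6 listed 3.22% (201 of 6245). The share was 1.04% in tumour 3, 0.588% in tumour 1 and 0.350% in tumour 9, and at most 0.0643% in tumours 5, 7 and 8. At 10 CPM, 197.5 reads would be expected in tumour 4 and 228.1 in tumour 2, so a count of 0 lay far outside the counting error of independent reads. Among genes of 1 to 10 CPM the order of these tumours was the opposite, with 53.1% at 0 in tumour 2 and 40.5% in tumour 4. Among genes of 100 to 1000 CPM, 1.12% were at 0 in tumour 4 and 0.343% in tumour 2, and no gene of 1000 CPM or more was at 0 in any tumour. The shares of tumours 2 and 4 at 10 to 100 CPM lie apart from those of the other 7, so no correlation of this share with depth is given.

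**Figure D1:**
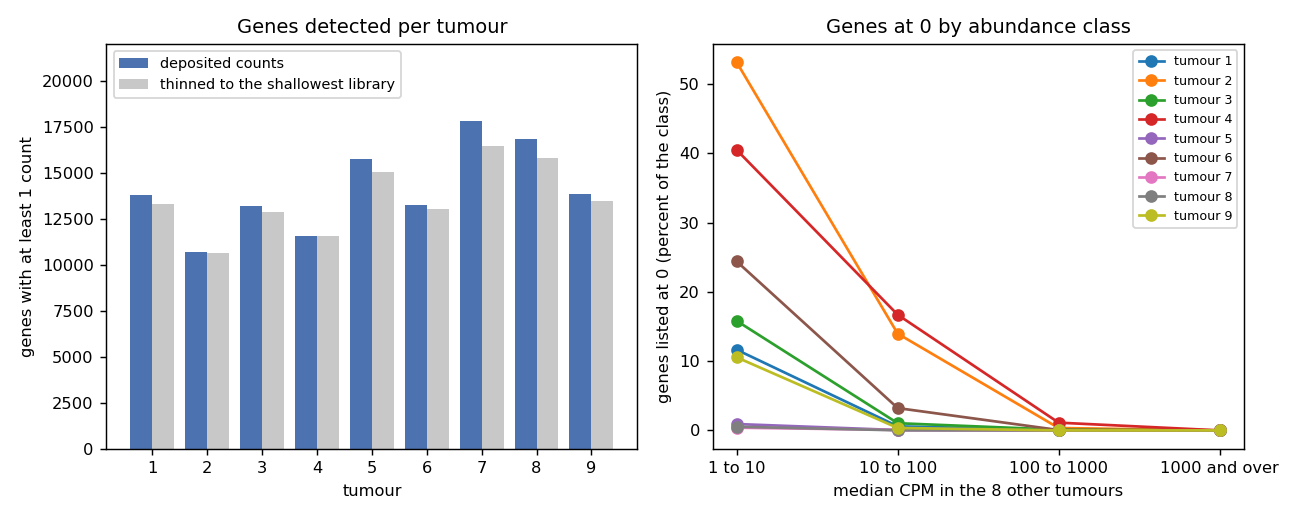
Left, genes with at least 1 count in each tumour (bars from 0), for the deposited counts and for counts thinned to the shallowest library. Right, percent of genes listed at 0 in each tumour, by the median CPM of the gene in the 8 other tumours; tumours 2 and 4 lie above the rest at 10 to 100 CPM, with 13.96% and 16.7%.

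The same 3 tumours were the least like the rest. Tumours 5, 7 and 8 had the closest profiles, with Pearson r of log2 CPM over 13558 genes of 0.92 between tumours 5 and 7, 0.91 between 5 and 8 and 0.91 between 7 and 8. These correlations run across genes, which are not independent replicates. The median r of a tumour with the 8 others was 0.39 for tumour 4, 0.61 for tumour 2 and 0.62 for tumour 6, and between 0.78 and 0.83 for the remaining tumours. Tumour 4 was closest to tumour 6, at r = 0.48. The first principal component held 35.7% of the variance and placed tumour 4 at 432.31, tumour 2 at 100.99 and tumour 6 at 48.72, with the 6 others between -100.36 and -91.20. The second held 27.2% and separated tumour 2, at 402.58. The score on the first component fell with log2 total counts (r = -0.86, p = 0.00176, adjusted p = 0.00528, exact permutation test), but not by rank (rho = -0.48, p = 0.194, adjusted p = 0.291, exact permutation test). Without tumours 2 and 4 r was -0.71. That value rests on tumour 6, which lay apart from the 6 others and had the lowest total left. The first component computed without tumours 2, 4 and 6 was another axis, on which tumour 3 lay farthest. On that axis r was -0.53, with an adjusted exact permutation p of 0.346. Over the 9 tumours, the relation of the first component to genes detected did not pass the threshold (r = -0.63, raw and adjusted p = 0.0634; rho = -0.37, raw and adjusted p = 0.336, exact permutation tests; r = -0.67 without tumours 2 and 7).

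**Figure D2:**
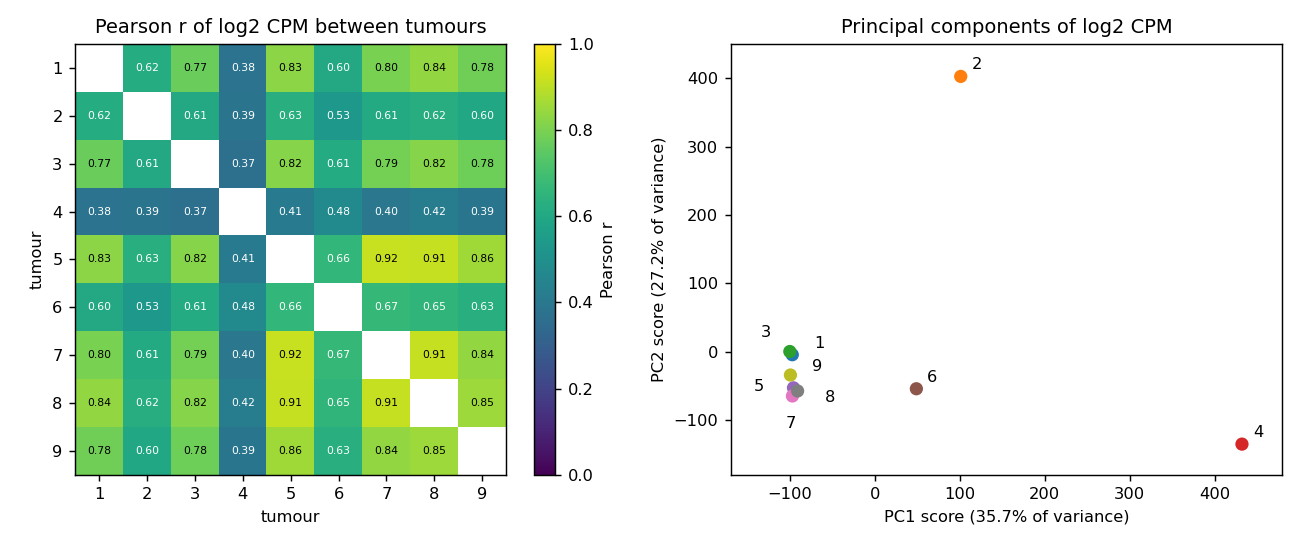
Left, Pearson r of log2 CPM for each pair of tumours (colour and printed value; the diagonal is left empty). Right, scores of the tumours on the first 2 principal components, 1 point per tumour; tumour 4 lies at 432.31 on the first and tumour 2 at 402.58 on the second, away from the 6 tumours at the left.

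How much a gene varied between tumours depended on its abundance. The median SD of log2 CPM over the 9 tumours was 3.27 for the 4274 genes with a mean of 1 to 10 CPM, 1.56 for the 6924 genes of 10 to 100 CPM and 0.71 for the 2353 genes of 100 CPM or more. Without tumours 2, 4 and 6 these medians were 2.17, 0.63 and 0.48, over 3695, 6511 and 2311 genes. A few tested genes fell below 1 CPM once normalisation factors were computed again and are in no class. The biological coefficient of variation at the dispersion trend, the relative SD of a gene between tumours beyond counting error, had medians of 2.22, 1.05 and 0.69 in these classes over 9 tumours, and of 1.32, 0.57 and 0.49 without tumours 2, 4 and 6.

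Against that trend, 785 of 13558 genes (5.79%) varied more than genes of like abundance in edgeR's deviance test at an adjusted p under 0.05, and 499 did so against the simulated reference, with 425 genes called by both. The 2 references judge the same deviances, so the shared calls are not independent support. On simulated data at the same dispersion trend, 40.1% of the 152 calls of the first kind and 5.68% of the 88 calls of the second were false. Those data followed the model behind the simulated reference, with every gene at the trend. These shares are therefore not error rates of the 785 and 499 calls. At an unadjusted p under 0.05 the counts were 2099 and 1525. Of the 785 genes, 150 had a mean of 100 CPM or more, 508 lay at 10 to 100 CPM and 127 at 1 to 10 CPM. The simulated reference called 140, 206 and 153 genes in these classes. Tumour 4 was the one farthest from the median of the others for 457 of the 785 genes, above the others for 263 and below for 194. Tumour 2 was farthest for 159 genes, mostly below the others (120), and tumour 6 for 30. Together these 3 tumours were farthest for 646 of the 785 genes and for 422 of the 499. Over all 13558 genes tested, tumour 4 was farthest for 5650, tumour 2 for 3464 and tumour 6 for 1584. The 3 tumours were thus farthest for most tested genes as well, so their joint share is not particular to the calls. The farthest tumour is taken on the log2 scale and need not be the one on which a call rests.

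Each of the 9 fits that left out 1 tumour kept between 434 and 695 of the 785 calls. The lowest number was without tumour 4 and the highest without tumour 6. A gene that fell below the abundance filter in a fit, and so was not tested, also counts as not kept. Without tumour 4, 13051 genes were tested. In all 9 fits 160 genes stayed past the threshold, and 148 of these also passed against the simulated reference. That reference judges the same deviances of the 9-tumour fit, so this overlap is not independent support. Without tumours 2, 4 and 6, 698 of 12518 genes passed (421 against the simulated reference), and 125 of them stayed past it in each of the 6 fits that left out 1 more tumour. The calls from 9 tumours and from 6 shared 257 genes, where independent lists of these sizes would share 33.2. Both fits used the same 6 libraries, so part of that overlap comes from the shared data. Of the 785 genes, 608 were still abundant enough to be tested in the 6 tumours. Against the simulated reference 134 genes were shared, where 9.81 would be by independence.

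**Figure D3:**
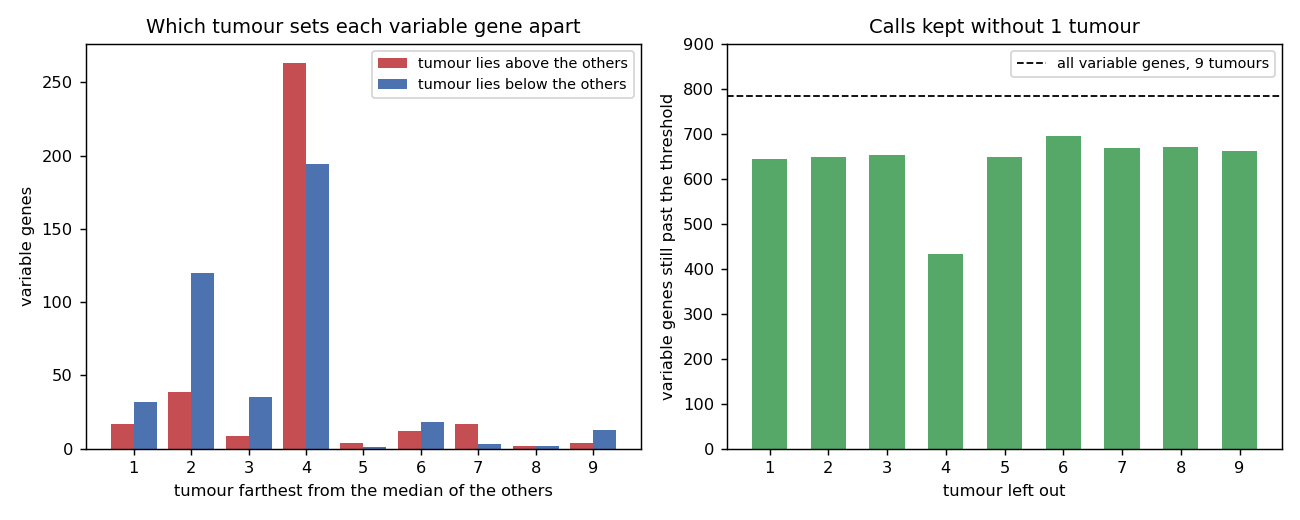
Left, number of the 785 variable genes for which each tumour is the one farthest from the median of the others, split by direction. Right, number of the 785 genes still past the threshold when the tumour on the x axis is left out (bars from 0, dashed line at 785). Tumour 4 was the farthest for 457 genes, and 434 genes were kept without it. The farthest tumour need not be the one on which a call rests.

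Among the genes past the threshold in every leave-one-out fit, ENSCAFG00000010090 had the largest excess variability with a tumour above the others, and ENSCAFG00000012272 with a tumour below. ENSCAFG00000010090 averaged 154 ± 383 CPM (SD, n = 9) and reached 1162 CPM in tumour 7, 192.6 CPM in tumour 4 and 28.0 CPM in tumour 2. It was at most 1.44 CPM in the 6 other tumours and was listed at 0 in tumour 3, whose floor is 0.0431 CPM. Its log2 excess was 4.30 (edgeR adjusted p = 2.17e-26). ENSCAFG00000012272 averaged 297 ± 720 CPM (SD, n = 9), with 2202 CPM in tumour 7, 252.6 CPM in tumour 5 and 138.8 CPM in tumour 9. It was listed at 0 in tumour 1, whose floor is 0.0327 CPM, and stood at 0.520 CPM in tumour 8 and at 1 count in tumour 2. Its log2 excess was 4.13 (edgeR adjusted p = 4.5e-23). Without tumours 2, 4 and 6 the excess of the 2 genes was 5.75 and 5.07. Without tumour 7, where both were highest, it was 2.58 and 2.94, still past the threshold. Without tumour 1, the farthest tumour of ENSCAFG00000012272, the excess of that gene was 3.79. It thus depended more on the high value in tumour 7 than on the 0 in tumour 1.

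Of the calls lost in at least 1 leave-one-out fit, 344 were lost in 1 fit only and 281 in more, genes no longer tested in a fit included. Both printed here were lost in 1 fit. ENSCAFG00000024869 was at 917.3 CPM in tumour 4 (20032 counts) and at 7.90 CPM in tumour 5, under 1 CPM in tumours 7 and 8, and at 0 in the other 5. Its log2 excess of 4.70 (edgeR adjusted p = 2.26e-36) fell to 0.94 without tumour 4 (adjusted p = 0.398). ENSCAFG00000025297 was at 516.7 CPM in tumour 6 and 67.7 CPM in tumour 4, between 0.239 and 11.5 CPM in 5 tumours, and at 0 in tumours 1 and 2. Its log2 excess of 3.55 (edgeR adjusted p = 4.29e-14) became 1.38 without tumour 6 (adjusted p = 0.127). Its farthest tumour on the log2 scale was tumour 1, at 0, although the call was lost without tumour 6.

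**Figure D4:**
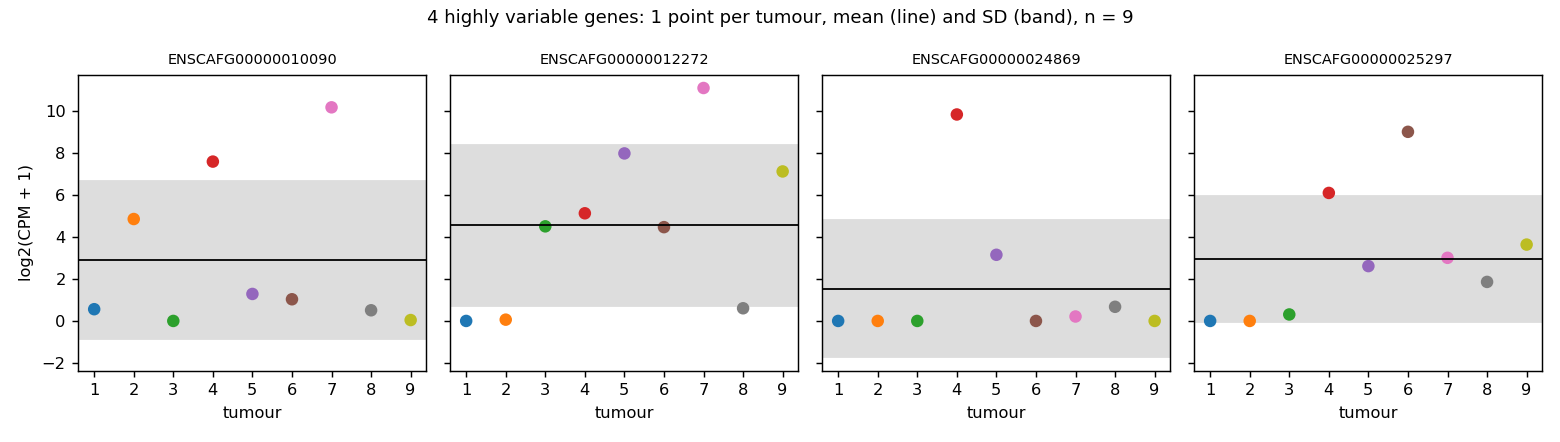
Log2(CPM + 1) of the 4 genes in each tumour, 1 point per tumour, with the mean (line) and 1 SD to either side (band) over the 9 tumours. ENSCAFG00000010090 and ENSCAFG00000012272 are highest in tumour 7, ENSCAFG00000024869 in tumour 4 and ENSCAFG00000025297 in tumour 6.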

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

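All tests of explanations in this part were chosen after the counts of genes at 0 had been seen. The 5 results come from Dixon's rule over 13 measures, which marks a tumour whose gap to its nearest neighbour is a large part of the whole range. Chance marks about 5% of measures, but these measures are not independent, and that share does not apply to principal components or to genes chosen for their spread.

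Tumour 4 stood apart by its median correlation with the others, 0.3932 against 0.6088 for the next lowest, and by its score of 432.31 on the first principal component. For the correlation the gap was 0.497 of the range, only just past the limit of the rule. For the component it was 0.622. Tumour 2 stood apart on the second component, at 402.58, and tumour 6 on the third, at 291.27. ENSCAFG00000024869 had a log2(CPM + 1) of 9.843 in tumour 4 against 3.154 in tumour 5, but it was chosen as a call lost without tumour 4, so this adds no evidence.

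These libraries are also the ones that list the most moderately abundant genes at 0. Depth alone is argued against: after thinning every library to the total of tumour 4, the highest share at 0 among the 6 other libraries was 1.165%, below the 3.22% to 16.7% of tumours 2, 4 and 6. A small number of RNA molecules entering the library may contribute. It was examined in the 1000 genes of 10 to 100 CPM steadiest in tumours 1, 3, 5, 7, 8 and 9. Of these, tumour 2 listed 9.3% at 0, tumour 4 13.2% and tumour 6 2.5%. The share was at most 0.1% in each of the 6 other tumours when its genes were chosen in the other 5. These genes come from the class whose shares at 0 had been seen. Another cell makeup or degraded RNA may leave the same genes at 0, so the values do not tell these causes apart. Whether few RNA molecules are the whole cause in tumour 4 stays open. Its 40.47% of genes of 1 to 10 CPM at 0, against 53.12% in tumour 2, compares 2 single libraries. Another cell makeup or tumour biology stays open for tumour 4, which had 73 genes of at least 30 CPM that were under 1 CPM in each other tumour: without gene names and with 1 library, these cannot be told apart from uneven amplification. No test of RNA degradation was made.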

How the results depend on the processing

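The number of variable genes, 785, moved by more than 1.5 times under these settings: 468 at a threshold of 0.01, 130 as DESeq2 dispersion outliers (all 130 among the 785), 170 with a filter at 100 CPM, 499 against the simulated reference and 421 against it without tumours 2, 4 and 6. The 499 and the 785 rest on the same deviances, so they differ through the reference distribution alone. For the 421 the tumours changed as well. For the DESeq2 count the cause was not tested. The filter at 100 CPM tests fewer genes (2351), and it also lowered the number past the threshold in every leave-one-out fit from 160 to 34. In the main fit 150 of the 2353 genes of 100 CPM or more were called, so 785 and 170 count calls over different sets of genes. DESeq2 size factors, no filter and a filter at 5 CPM stayed within 1.5 times. So did each leave-one-out fit and the fit without tumours 2, 4 and 6. These settings gave 632 to 886 genes. The number of genes tested differed too, at 20181 with no filter and 10858 at 5 CPM against 13558. Like counts are therefore not like shares of the genes tested. Without tumour 4 the genes called changed more than their number, with 728 calls, of which 434 were among the 785. Without tumour 5, 7 or 8 every call (648, 668 and 671) was among the 785. Shared calls were not counted for the size factors and filters. The share of variance on the first component was 33.1% to 38.6% under other scalings, filters up to 5 CPM and prior counts, and 35.1% without tumours 2, 4 and 6. It rose to 48.6% without tumour 2, 43.1% without tumour 4, 41.6% without tumour 6 and 43.6% at 100 CPM. The correlation of the first component with log2 total counts passed the threshold in 14 other settings and not without tumours 2, 4 and 6. The component is another axis without tumour 4, where tumour 2 lay farthest (417.95), and without tumours 2, 4 and 6, where tumour 3 did (214.84), so these values do not test the same relation. That with genes detected passed the threshold with no filter (r = -0.68), with a prior count of 0.5 (r = -0.67) and without tumour 4 (r = -0.75); the cause was not tested. The alternatives for gene lists and their correlations, log-scale variance included, were not run, because the identifiers could not be matched to symbols. No paired analysis was possible because there is 1 group. Depth had a small effect on detection at 1 to 10 CPM: thinning raised the share at 0 from 11.6% to 13.1% in tumour 1 and from 0.391% to 0.716% in tumour 7.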

Other observations

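Some genes were far more abundant in 1 tumour than in the others, though not shown to be absent there. At 30 CPM or more in 1 tumour and under 1 CPM in each of the 8 others there were 73 genes in tumour 4, 20 in tumour 2, 4 in tumour 6, 2 in tumour 8 and 1 in tumour 1, and 0 in tumours 3, 5, 7 and 9. The reverse, a gene listed at 0 in 1 tumour and at 10 CPM or more in each of the others, was seen for 328 genes in tumour 4, 173 in tumour 2 and 17 in tumour 6, for 1 gene each in tumours 1, 3 and 9, and for 0 genes in tumours 5, 7 and 8.

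Genes with consecutive identifier numbers shifted together in some tumours; the tests here were chosen after the pattern was seen. The 9298 genes with a mean of at least 10 CPM were ordered by identifier and divided into 92 blocks of 100, and the block median of the deviation from the other tumours was set against 1000 shuffles of the order. At a family-wise 0.05 per tumour, 12 pairs of a block and a tumour passed, in 7 of the 9 tumours, where 0.45 tumours with a false block would be expected. In the measured values with shuffled identifiers 1 pair passed, and a shift of 0.5 planted in tumour 7 (limit 0.317) was recovered; a shift of that size lies under the limits of tumours 2, 4 and 6 (0.824, 0.972 and 0.508). A single block accounts for 7 of the 12 pairs, higher in tumours 4, 6, 7 and 8 (shifts of 1.06, 0.54, 0.49 and 0.39 on the log2 scale) and lower in tumours 1, 3 and 9 (-0.55, -0.53 and -0.36). No pair passed in any other tumour, so the count of 7 tumours rests largely on that block. Tumour 2 had a shift of -0.68 there, which did not pass (p = 0.2, permutation test). The blocks directly before and after it in identifier order shifted in the same direction in each of these 7 tumours. Both passed in tumour 7, at 0.46 and 0.35, so the pattern extends beyond 1 block. Each shift is a deviation from the other tumours, so the 7 pairs are not independent, and higher values in some tumours in part force lower values in others. Related neighbouring genes stay open: at least 66% of the genes lay on the side of the shift in each block that passed, but blocks chosen by their median must show such a share. Gains and losses of chromosome segments, with the largest shift at 1.06, and a bias between libraries that follows sequence content, which may move the same block in many tumours (here 7, a count that the centring in part sets), cannot be told apart, because neither positions nor sequences of the identifiers were at hand.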
